A study of Mus musculus with 18 samples.

How the data were processed

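Transcript levels were measured in total RNA of terminal bronchiolar epithelial cells from mouse lung, on 18 Affymetrix Mouse Gene ST arrays hybridised with biotin-labelled target. The values analysed were the table deposited for the series, in which each probe set has 1 log2 value per array. They had been made with RMA, per the submitters' processing notes, a procedure that corrects background, normalizes between arrays and summarises the probes of a probe set on the log2 scale. The version of RMA, the genome build and any filter were not given in the sources used here. No scanner files were used, so background and saturation of single probes were not examined, and the number of arrays limits the precision. The deposited log2 values ran from 2.53 to 13.93, and the median of an array lay between 6.48 and 6.65.

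Of 35557 probe sets, 21789 had 1 gene symbol in the platform annotation, 1621 had several and 12147 had none. The last 2 kinds were left out of all comparisons between groups, and the number of them that passed the test is given in the closing section. Where a gene had more than 1 probe set, as 999 genes did, the probe set with the highest mean over all arrays was kept, which left 19938 genes. Symbols were checked through gene identifiers against the RefSeq gene table of assembly GRCm38.p6, which held 19855 of the genes, and 0 symbols needed an update. No coordinates are given, because no build was named for the deposited values.

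Arrays were grouped by the genotype and time in their labels, which gave 6 groups of 3 arrays: control and Cebpa d/d, each at 0, 3 and 72 hr. Tests were run in R 4.3.3 with limma 3.58.1. A single linear model of the 6 group means was fitted to all 18 arrays without a replicate term, so all groups shared an estimate of the spread with 12 residual degrees of freedom, to which empirical Bayes moderation added 4.49. It gave 10 contrasts: Cebpa d/d minus control at each time and as a mean over the 3 times, 3 hr minus 0 hr and 72 hr minus 0 hr in each genotype, and the 2 interactions, which are the time change in Cebpa d/d less that in control. P-values were adjusted by Benjamini-Hochberg over the 19938 genes within a contrast, and a gene was said to have passed, to be higher or lower, or to have risen or fallen, at an adjusted p under 0.05. Every difference is on the log2 scale with its standard error (SE), between groups of 3 arrays.

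Gene lists written from textbook knowledge of lung cell types, naphthalene injury and proteases and their inhibitors were fixed before the data were examined. So were the tests of the contrasts and lists and the rule for naming genes. Tests of single arrays and of muscle genes came later. Of 28 lists, 27 had at least 5 measured members and were tested; the list of red blood cell markers did not reach that number. Each list was tested with camera, which compares its members with all other genes, at a preset correlation of 0.01, with adjustment over the 27 lists within a contrast. Because members of a list vary together, camera was also run with an estimated correlation: of 96 list calls at the preset value, 3 held, namely the oxidative stress and NRF2 list at 3 hr in Cebpa d/d and the mitosis list at 72 hr in both genotypes. The rotation test fry, which asks whether members move on balance one way, was run beside them. For each list the number of members that passed is given over all genes and adjusted over the list alone. The lists of basal cell, neuroendocrine cell, lipid and sterol synthesis and sex-linked transcripts passed the set test in no contrast with all arrays and no sex term, with smallest adjusted p values of 0.235, 0.156, 0.16 and 0.234 at the preset correlation. At most 3, 1, 2 and 0 of their members passed in any contrast. A list of cardiac and a list of skeletal muscle genes were added after the values had been seen.

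Genes were named by rule. Cebpa came first. In each contrast, among genes that passed and whose 2 groups of arrays did not overlap, the 8 largest positive and 8 largest negative differences were taken. Interactions had no condition on overlap. From each list that passed the set test or had at least 3 members that passed, up to 4 members with the smallest adjusted p were taken. In all contrasts 12 anchor genes were followed: Cebpa, Scgb1a1, Cyp2f2, Foxj1, Sftpc, Slpi, Serpinb1a, Timp1, Ctss, Ctsk, Mmp14 and Mki67. Where fewer than 5 genes passed, the 5 with the smallest unadjusted p were added with their values. The examples in the text come from those sets, and other genes are said to have been chosen after their values were seen.

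Alternatives recomputed the counts of genes: leaving out genes below the median level, the mean of all probe sets of a gene, a moderated variance with trend and robust fit, array weights, the replicate number as a block, only the groups of a contrast in the fit, each array centred on its median, an unadjusted p under 0.05 with at least 1.5-fold change, and leaving out each array in turn. The fit with only the groups of a contrast was not run for the mean over the 3 times, which uses all groups. Counts of lists were recomputed without genes below the median level, with the replicate block, with each array centred, with each array left out, with sex, without both arrays that stood apart, with an estimated correlation and with fry. Sex as a covariate, read from Xist and Eif2s3y, and a fit without both arrays that stood apart were added after the data had been seen. Up to 100 other splits of the arrays between groups were drawn for each contrast. The scripts for the tests were run first on simulated data, with 200 of 19938 genes changed. For the genotype difference at 0 hr, 40.3% of changes of 0.5 log2 units, 91% of changes of 1 and 100% of changes of 2 were recovered. At 3 hr these shares were 46.3%, 92.5% and 100%, and at 72 hr they were 58.2%, 91% and 97%. Of the genes called there, 4.9%, 8.1% and 5.2% had not been changed. A simulation with no change gave 0 calls in limma over the 10 contrasts, and 1 of 1 shifted list of 30 genes and 0 of 20 unshifted lists passed camera. Simulated genes varied independently of each other, so this could not test the preset correlation in camera. Recovery with other numbers of changed genes was not simulated. Each simulated gene had the same normal spread in all groups, and no simulated array stood apart. The real arrays differ in both respects, so these shares do not give the recovery there. Cebpa itself did not pass at any single time with all arrays. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.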

Results

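The arrays followed terminal bronchiolar epithelial cells of mouse lung after injury with naphthalene, which the cytochrome P450 Cyp2f2 of club cells turns into a toxic product. The mice had a mixed FVB/N and C57BL/6 background and belonged to 2 genotypes, called control and Cebpa d/d in the labels. Cebpa encodes the transcription factor C/EBP alpha. Each genotype was sampled at 0, 3 and 72 hr, with 3 arrays per group and 18 arrays in all. The median over all probe sets lay between 6.48 and 6.65 on the log2 scale in every array, and arrays of the same group correlated across probe sets at 0.982 or more. The labels number the replicates without saying that they came from separate animals, so p-values measure the spread between these samples, which may be technical in part. Scgb1a1, the main secretory protein of club cells, had group means of 12.68 to 12.84, where the highest value of any probe set was 13.93. Saturation was not examined, so a steady level of Scgb1a1 may hide a change. Transcripts of other lung cells were present in all 6 groups: group means of the alveolar type 2 gene Sftpc were 13.03 to 13.23, and those of the smooth muscle gene Myh11 were 10.28 to 10.89. By the transcripts Xist and Eif2s3y, all 3 arrays of both 72 hr groups were from females, against 1 of 3 in each group at 0 and 3 hr. Each group at 0 and 3 hr therefore came from more than 1 animal, while for the 72 hr groups this stays open.

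The Cebpa probe set (10552140) was read in every array first, since it checks the labels. In control arrays the log2 level was 7.89, 10.07 and 10.17 at 0 hr, 10.30 to 10.52 at 3 hr and 9.69 to 9.87 at 72 hr. Cebpa d/d arrays had 7.83 to 8.27 at 0 hr, 8.07 to 8.37 at 3 hr and 9.07, 8.55 and 7.90 at 72 hr. The array labelled control 0 hr replicate 1 therefore went against its label, with a level of 7.89 inside the range of the Cebpa d/d arrays. As a mean over the 3 times Cebpa was lower in Cebpa d/d by a log2 difference of -1.58 ± 0.24 (SE; adjusted p = 0.00953). At the single times the differences of -1.31 ± 0.42 (adjusted p = 0.309), -2.14 ± 0.42 (adjusted p = 0.152) and -1.28 ± 0.42 (adjusted p = 0.609) did not pass. Without the array labelled control 0 hr replicate 1 they were -2.05, -2.14 and -1.28, and all passed (adjusted p = 0.000696, 0.000186 and 0.0144). The probe set covers the transcript as a whole and the labels do not say which part of the gene the d/d allele alters, so the level left in Cebpa d/d arrays does not measure intact transcript. Every direction below that involves the control group at 0 hr includes the array labelled control 0 hr replicate 1.

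**Figure D1:**
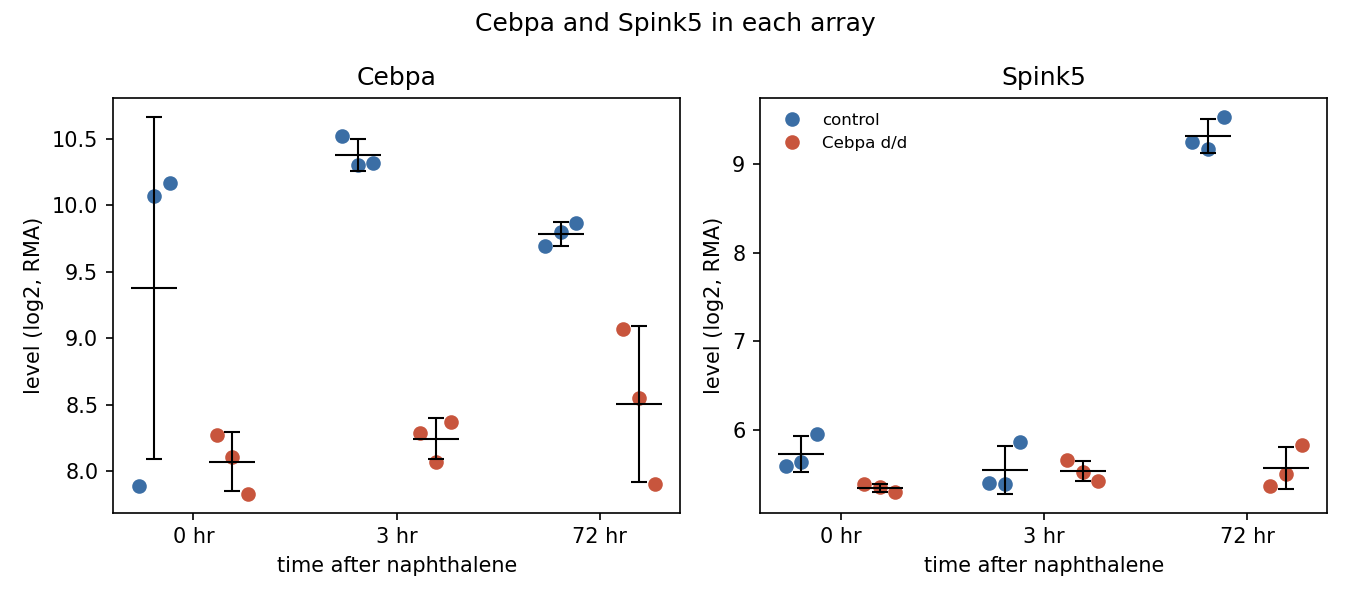
Log2 levels of Cebpa and of Spink5 in each of the 18 arrays, by genotype (control in blue, Cebpa d/d in red) and hours after naphthalene; dots are arrays, and black bars are the mean ± SD of 3 arrays. The array labelled control 0 hr replicate 1 has Cebpa at 7.89, among the Cebpa d/d arrays, and Spink5 has a mean of 9.31 in control arrays at 72 hr against 5.35 to 5.73 in the other 5 groups.

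The comparison of genotypes at 0 hr asked how Cebpa d/d samples differed from control samples at the start of the time course. Of 19938 genes, 65 were higher and 2 were lower in Cebpa d/d. The largest differences were in genes of heart muscle: Hamp, the iron hormone hepcidin, which heart muscle also makes, was higher by 3.67 ± 0.53 (adjusted p = 0.00317). The sarcomere genes Ttn (2.69 ± 0.32, adjusted p = 0.000456) and Myl3 (2.63 ± 0.30, adjusted p = 0.00039) and the myoglobin gene Mb (2.59 ± 0.40, adjusted p = 0.005) were higher too. These SE and p-values rest on the spread pooled over all 6 groups, which can understate the spread at 0 hr. Hamp had an SD of 1.18 in control and 1.17 in Cebpa d/d at 0 hr, against 0.27 to 0.61 in the other groups. With only the 0 hr groups in the fit, 1 of the 67 genes passed. On a list of 32 cardiac muscle genes, written after the values were seen, 20 were higher and 0 lower. The trefoil peptide gene Tff2 was higher by 1.18 ± 0.21 (adjusted p = 0.0156), 1 of 20 mucous cell markers that passed over all genes and adjusted over the list alone (camera adjusted p = 0.0215, and 0.678 with an estimated correlation). The 2 lower genes were Efcab10 (-0.65 ± 0.12, adjusted p = 0.0269) and Ift80 (-0.57 ± 0.10, adjusted p = 0.0157), which encodes a transport protein of cilia. Ciliated cell markers lay lower as a list, with a median of -0.49 over 39 genes (camera adjusted p = 1.21e-22, adjusted p = 0.479 with an estimated correlation). Of them 0 passed limma over all genes and 16 were lower adjusted over the list alone. At an unadjusted p under 0.05 there were 1700 genes, where 997 are expected by chance. Interferon-stimulated genes had a median of -0.23 over 33 genes with 0 called over all genes or over the list alone (camera adjusted p = 0.000358, adjusted p = 0.942 with an estimated correlation). Levels of the club cell genes Scgb1a1 (0.09 ± 0.08, adjusted p = 0.84) and Cyp2f2 (-0.12 ± 0.12, adjusted p = 0.851) did not differ by more than the spread.

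Between the genotypes at 0 hr, 2265 genes had arrays that did not overlap, where chance gives 10% of genes. The array labelled control 0 hr replicate 1 is part of this comparison. Without it 78 genes were higher and 75 lower, 2 ciliated markers were lower over all genes, and the interferon list no longer passed and turned upward (camera adjusted p = 0.473), while the neuroendocrine list passed as higher (0.0074). Without Cebpa d/d 72 hr replicate 1 the club cell list passed as lower (0.00589). The count was 31 without control 0 hr replicate 3, and 30, 39 and 120 without Cebpa d/d 0 hr replicates 1, 2 and 3. Hamp, Ttn, Myl3 and Mb passed without any 1 array. Tff2 did not without Cebpa d/d 0 hr replicate 1 or 2 (adjusted p up to 0.123). Ift80 did not without either of these or control 0 hr replicate 3 (up to 0.128), and Efcab10 did not without any of those or Cebpa d/d 0 hr replicate 3 (up to 0.193).

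At 3 hr the question was how the genotypes differed early after injury. Only 3 genes passed, all higher in Cebpa d/d. They were Rwdd2a (0.90 ± 0.10, adjusted p = 0.00297), Chac1, which breaks down glutathione (0.88 ± 0.13, adjusted p = 0.0326), and the glucose transporter gene Slc2a3 (0.58 ± 0.09, adjusted p = 0.0326). The calcium-binding gene S100g (-1.55 ± 0.27, adjusted p = 0.103) and the neutrophil chemokine gene Cxcl5 (1.35 ± 0.24, adjusted p = 0.136) had the next smallest p-values and did not pass. Of 38 immediate early genes 0 passed limma over all genes and 1 was higher adjusted over the list alone, with a median of 0.20 (camera adjusted p = 1.63e-06, adjusted p = 0.683 with an estimated correlation). Fibroblast markers lay higher with 0 of 25 called either way (median 0.14, camera adjusted p = 4.55e-05, adjusted p = 0.683 with an estimated correlation). Neutrophil markers lay lower with 0 of 18 called (median -0.23, camera adjusted p = 0.00328, adjusted p = 0.683 with an estimated correlation). Lists of mitosis (0.00349), smooth muscle (0.00961), p53 target (0.00963), heat shock and unfolded protein (0.0133) and interferon-stimulated genes (0.0359) lay higher by camera adjusted p, each over 0.6 with an estimated correlation. Among alveolar type 2 markers, 0 of 25 passed over all genes while 5 were higher and 8 lower adjusted over the list alone.

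At 3 hr, 1001 genes had an unadjusted p under 0.05 between the genotypes, where 997 are expected by chance. Arrays of the genotypes did not overlap for 1952 genes, where chance gives 10%. The count of 3 was 15 without the array labelled control 0 hr replicate 1 and 5 without Cebpa d/d 72 hr replicate 1, which enter only through the shared spread. It was 1 without any single array among control 0 hr replicate 2, control 3 hr replicate 3, the 3 control 72 hr arrays, the 3 Cebpa d/d 0 hr arrays, Cebpa d/d 3 hr replicate 3 and Cebpa d/d 72 hr replicate 2. Rwdd2a passed without any 1 array. The other 2 genes lost their call without 13 and 14 of the 18 arrays in turn (adjusted p up to 0.194 for Chac1 and 0.327 for Slc2a3).

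At 72 hr the comparison asked how the genotypes differed during recovery, when protease and anti-protease genes were of interest to the study. Of the genes tested, 2 were higher and 12 lower in Cebpa d/d. Spink5 (probe set 10455395), which encodes a serine protease inhibitor of epithelia, was lower by -3.75 ± 0.15 (adjusted p = 1.92e-10). Its levels were 9.17 to 9.53 in control arrays and 5.37 to 5.83 in Cebpa d/d arrays. Also lower were the secreted protein gene Sectm1b (-2.12 ± 0.25, adjusted p = 0.00204), S100g (-2.02 ± 0.27, adjusted p = 0.00262) and the acute phase gene Orm2 (-1.94 ± 0.27, adjusted p = 0.00412). Bex2 (-1.68), the chitinase gene Chia1 (-1.46), Cd7 (-1.17) and the histone gene H3c15 (-1.19) were lower as well. Copies of histone genes are near-identical, so H3c15 is uncertain. Pigr, the receptor that carries antibodies across epithelia, was higher by 1.95 ± 0.29 (adjusted p = 0.0074). Spink5 was the 1 of 50 anti-protease genes that passed over all genes. On that list 4 were lower adjusted over the list alone, with a median of -0.07 (camera adjusted p = 0.000282, adjusted p = 0.0911 with an estimated correlation). Slpi, an inhibitor of neutrophil elastase, differed by -0.68 ± 0.27 (adjusted p = 0.741) and did not pass. Of 58 protease genes 0 passed limma over all genes and 1 was lower adjusted over the list alone (median -0.08, camera adjusted p = 0.00217, adjusted p = 0.347 with an estimated correlation). The cysteine protease gene Ctss differed by -0.39 ± 0.23 (adjusted p = 0.828).

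Alveolar type 2 markers at 72 hr lay lower in Cebpa d/d, with 0 of 25 called over all genes, 1 higher and 8 lower adjusted over the list alone and a median of -0.29 (camera adjusted p = 9.34e-09, adjusted p = 0.0911 with an estimated correlation). Ciliated cell markers had a median of -0.22 with 0 of 39 called (camera adjusted p = 2.82e-07, adjusted p = 0.464 with an estimated correlation). Macrophage markers had a median of -0.24 with 0 of 26 called over all genes (camera adjusted p = 2.67e-05, adjusted p = 0.347 with an estimated correlation), and neutrophil markers one of -0.21 with 0 of 18 called (camera adjusted p = 0.000363, adjusted p = 0.347 with an estimated correlation). Smooth muscle (median -0.22, camera adjusted p = 3.95e-05), fibroblast (-0.16, 3.82e-05) and cytokine genes (median -0.004, mean -0.14, 0.0241) lay lower with 0 called, at adjusted p values of 0.347, 0.369 and 0.657 with an estimated correlation. Interferon-stimulated genes lay higher (median 0.19 over 33, 0 called, camera adjusted p = 0.0281, adjusted p = 0.657 with an estimated correlation). Mucous cell markers lay higher with a median of 0.21, and Pigr was the 1 of 20 called over all genes and over the list alone (camera adjusted p = 0.0021, adjusted p = 0.274 with an estimated correlation). At an unadjusted p under 0.05, limma gave 1259 genes, where 997 are expected by chance, and 3008 genes did not overlap, where chance gives 10%. Pigr (adjusted p = 0.0538) and Chia1 (adjusted p = 0.0508) lost their call without control 72 hr replicate 1. Without Cebpa d/d 72 hr replicate 1 the protease, smooth muscle, fibroblast, cytokine and macrophage lists lost theirs (camera adjusted p = 0.298, 0.174, 0.373, 0.291 and 0.0582). The club cell (4.44e-05) and xenobiotic metabolism lists (4.34e-05) then passed as lower in Cebpa d/d, and the mitosis list (5.32e-09) as higher.

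The mean genotype difference over the 3 times asked which genes differed on average, which includes genes that differed at 1 time only: 27 were higher and 34 lower in Cebpa d/d. Of the higher genes 5 were on the added cardiac list, whose median difference was 1.63 at 0 hr, 0.06 at 3 hr and 0 at 72 hr. The lysozyme genes Lyz1 (-1.68 ± 0.27, adjusted p = 0.0158) and Lyz2 (-1.29 ± 0.19, adjusted p = 0.00541), the surfactant lipid transporter gene Abca3 (-0.37 ± 0.06, adjusted p = 0.00999) and the peroxisomal oxidase gene Acoxl (-0.59 ± 0.08, adjusted p = 0.00242) were among the lower genes. Of 25 type 2 markers 1 was higher and 6 were lower over all genes, and 4 were higher and 10 lower adjusted over the list alone (camera adjusted p = 0.000508, adjusted p = 0.407 with an estimated correlation). Sequences of the 2 lysozyme genes are alike, so they may not be independent. Lyz2 was also on the macrophage list, so its lower level need not come from type 2 cells. Lcn2, an iron-binding defence protein on the neutrophil list, was lower by -1.81 ± 0.26 (adjusted p = 0.00541), the 1 of 18 called over all genes and 1 of 3 adjusted over the list alone (camera adjusted p = 0.000141, adjusted p = 0.407 with an estimated correlation). Tekt2, a protein of cilia, was lower by -0.57 ± 0.11 (adjusted p = 0.038), the 1 of 39 ciliated markers called over all genes, with 12 lower adjusted over the list alone (median -0.23, camera adjusted p = 4.01e-16, adjusted p = 0.407 with an estimated correlation). Pigr (0.85 ± 0.17, adjusted p = 0.0385) and Tff2 (0.60 ± 0.12, adjusted p = 0.0423) were the 2 of 20 mucous markers called, with 3 adjusted over the list alone (camera adjusted p = 0.00012, adjusted p = 0.213 with an estimated correlation). Immediate early genes lay higher with 0 of 38 called (median 0.08, camera adjusted p = 0.00558, adjusted p = 0.972 with an estimated correlation).

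Of 10 named genes that passed for this mean, 6 passed without any 1 array and 7 with sex as a covariate. Tekt2, Pigr and Tff2 each lost their call without 13 of the 18 arrays in turn (adjusted p up to 0.0983, 0.0966 and 0.105). The higher gene Fam78b (0.42 ± 0.08, adjusted p = 0.0275) lost it without 11 (up to 0.0746). The count of 61 was 201 without the array labelled control 0 hr replicate 1 and 116 without Cebpa d/d 0 hr replicate 3. It was 28 without control 0 hr replicate 3, 38 without control 3 hr replicate 1, and 36, 22 and 40 without control 72 hr replicates 1, 2 and 3. It was 24 and 26 without Cebpa d/d 0 hr replicates 1 and 2, 24, 34 and 33 without Cebpa d/d 3 hr replicates 1, 2 and 3, and 34 and 26 without Cebpa d/d 72 hr replicates 2 and 3. With each array centred on its median, 12 genes were higher and 32 lower. Without Cebpa d/d 72 hr replicate 1 the club cell (camera adjusted p = 0.000674) and xenobiotic lists (0.0347) passed as lower and mitosis (0.000737) as higher. Without the array labelled control 0 hr replicate 1 the interferon-stimulated (0.00163) and neuroendocrine lists (0.0109) passed as higher. Without both of these arrays, a fit chosen after the values were seen, the type 2 list no longer passed (0.0697). Across all genes, the genotype differences at 0, 3 and 72 hr correlated at 0.105 to 0.207, and no gene passed at more than 1 time in the same direction. Genes are not independent replicates.

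The change from 0 to 3 hr in control cells asked what the early response to naphthalene was: 374 genes rose and 323 fell. Genes of the oxidative stress response rose. The cystine transporter gene Slc7a11 rose by 5.02 ± 0.30 (adjusted p = 4.92e-08), the haem oxygenase gene Hmox1 by 3.96 ± 0.15 (adjusted p = 1.74e-10) and Srxn1, which restores peroxiredoxins, by 2.55 ± 0.14 (adjusted p = 1.57e-08). Of 40 oxidative stress and NRF2 targets 21 rose, and 25 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.97e-21, adjusted p = 0.0857 with an estimated correlation). Immediate early genes rose in 17 of 38 cases, 27 adjusted over the list alone (camera adjusted p = 6.25e-18, adjusted p = 0.178 with an estimated correlation). They were led by Myc (2.75 ± 0.28), Atf3 (2.67 ± 0.27) and Egr1 (2.51 ± 0.26). Heat shock and unfolded protein genes rose in 14 of 43 cases, and 20 rose and 1 fell adjusted over the list alone (camera adjusted p = 4.86e-08, adjusted p = 0.178 with an estimated correlation). Among them were Asns (1.92 ± 0.17), Ddit3 (1.33 ± 0.16) and Dnajb9 (1.21 ± 0.14). The prostaglandin synthase gene Ptgs2 rose by 2.05 ± 0.24 (adjusted p = 0.000139), 1 of 2 called among 49 cytokine and NF-kB genes over all genes and over the list alone (camera adjusted p = 0.000878, adjusted p = 0.524 with an estimated correlation). The heat shock gene Hspa1a (2.79 ± 0.37), the metallothionein gene Mt2 (3.22 ± 0.37) and the keratin gene Krt8 (1.12 ± 0.21, adjusted p = 0.00926) rose too. Of 51 epithelial repair genes 6 rose and 2 fell, and the list did not pass (camera adjusted p = 0.386) but did without the array labelled control 0 hr replicate 1 (0.0455).

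Some markers of other lung cells fell in control cells by 3 hr. Endothelial genes fell in 6 of 22 cases, 17 adjusted over the list alone, such as Tek (-0.93 ± 0.17, adjusted p = 0.00773) and Ptprb (-0.76 ± 0.12, adjusted p = 0.00336), with camera adjusted p = 1.01e-11 (adjusted p = 0.178 with an estimated correlation). Fibroblast genes fell in 5 of 25 cases, 14 adjusted over the list alone, such as Tcf21 (-0.92 ± 0.18, adjusted p = 0.0102), with camera adjusted p = 4.87e-10 (adjusted p = 0.178 with an estimated correlation). Smooth muscle genes fell in 5 of 14 cases, 8 adjusted over the list alone (camera adjusted p = 7.72e-07, adjusted p = 0.182 with an estimated correlation). Alveolar type 1 genes fell in 3 of 20 cases, 8 adjusted over the list alone, such as Rtkn2 (-1.04 ± 0.20) and Akap5 (-0.74 ± 0.14; camera adjusted p = 8.49e-05, adjusted p = 0.194 with an estimated correlation). Type 2 genes fell in 2 of 25 cases, 3 adjusted over the list alone (0.000106, adjusted p = 0.182 with an estimated correlation). Interferon-stimulated genes fell in 3 of 33 cases, 17 adjusted over the list alone (camera adjusted p = 1.67e-11, adjusted p = 0.182 with an estimated correlation). Mitosis genes fell in 6 of 93 cases, and 2 rose and 7 fell adjusted over the list alone (camera adjusted p = 0.000271, adjusted p = 0.599 with an estimated correlation). The club cell list lay lower with 0 of 27 called (0.00321, adjusted p = 0.524 with an estimated correlation). Scgb1a1 (-0.02 ± 0.08, adjusted p = 0.927) and Cyp2f2 (-0.14 ± 0.12, adjusted p = 0.548) did not change by more than the spread. Among 58 proteases 2 rose and among 50 anti-proteases 1 fell. Neither list passed (camera adjusted p = 0.569 and 0.45), and 5 anti-proteases rose and 3 fell adjusted over the list alone.

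The array labelled control 0 hr replicate 1 enters these changes, and without it 309 genes passed. The counts were then 20 for oxidative stress, 11 for immediate early, 12 for heat shock, 2 for endothelial, 1 each for fibroblast, smooth muscle and mitosis, and 0 for interferon-stimulated and type 2 genes. Control cells gave 279 genes at 3 hr without control 0 hr replicate 3, and 1414, 310 and 231 without control 3 hr replicates 1, 2 and 3. Of 65 named genes that passed, 24 did so without any 1 array, and every gene given a value for this change and said to have risen or fallen is among the 24.

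From 0 to 3 hr 531 genes rose and 343 fell in Cebpa d/d cells. The same stress genes rose: Slc7a11 rose by 5.19 ± 0.30 (adjusted p = 2.95e-08), Hmox1 by 4.29 ± 0.15 (adjusted p = 4.75e-11) and Srxn1 by 2.46 ± 0.14 (adjusted p = 2.81e-08). Of the oxidative stress and NRF2 list 21 of 40 rose, and 25 rose and 1 fell adjusted over the list alone (camera adjusted p = 8.64e-32, adjusted p = 0.0201 with an estimated correlation). Of immediate early genes 21 of 38 rose, 27 adjusted over the list alone (camera adjusted p = 5.28e-27, adjusted p = 0.0798 with an estimated correlation). Of heat shock and unfolded protein genes 14 rose and 1 fell, 18 and 2 adjusted over the list alone (camera adjusted p = 5.16e-10, adjusted p = 0.132 with an estimated correlation). Chac1 rose by 1.97 ± 0.13 (adjusted p = 1.58e-07), against 1.12 ± 0.13 (adjusted p = 0.000158) in control. Of 49 cytokine and NF-kB genes 5 rose, 8 adjusted over the list alone, among them Ptgs2 (2.38 ± 0.24), Lif (1.29 ± 0.18) and Cxcl5 (1.53 ± 0.24; camera adjusted p = 4.46e-05, adjusted p = 0.509 with an estimated correlation). Endothelial genes fell in 4 of 22 cases, 12 adjusted over the list alone, with Tek at -0.97 ± 0.17 (camera adjusted p = 5.98e-11, adjusted p = 0.26 with an estimated correlation). Ciliated markers rose in 3 of 39 cases over all genes and over the list alone (camera adjusted p = 0.00269, adjusted p = 0.686 with an estimated correlation). The largest falls were in heart muscle genes, 27 of the 32 on the added cardiac list, such as Hamp (-4.36 ± 0.53, adjusted p = 0.000106) and Myh6 (-3.44 ± 0.53, adjusted p = 0.001), both of them higher in the Cebpa d/d arrays at 0 hr.

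Both genotypes shared much of the early response: 240 genes rose in both, where independent lists would share 9.96, and 79 fell in both, where they would share 5.56. The group means compared share no arrays, and the changes correlated at 0.643 across all genes. Both sets of calls use the same estimate of the spread of each gene, so they are not independent. The values of 9.96 and 5.56 are thus not the overlap by chance. For the d/d count of 874 the values were 480 without Cebpa d/d 0 hr replicate 2, and 425 and 402 without Cebpa d/d 3 hr replicates 1 and 3. The interaction at 3 hr passed for 0 genes in limma, with 1365 at an unadjusted p under 0.05, where 997 are expected by chance. Its smallest p-values belonged to Xirp2 (-2.17 ± 0.32), Actn2 (-1.95 ± 0.30), Myl3 (-2.62 ± 0.42) and Myom1 (-0.89 ± 0.14), all muscle genes with adjusted p = 0.0572. Rwdd2a came next (0.85 ± 0.15, adjusted p = 0.0674). It passed for 44 genes without Cebpa d/d 0 hr replicate 3, 14 without control 0 hr replicate 2, and 1 each without control 3 hr replicate 2 and Cebpa d/d 3 hr replicate 3.

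**Figure D2:**
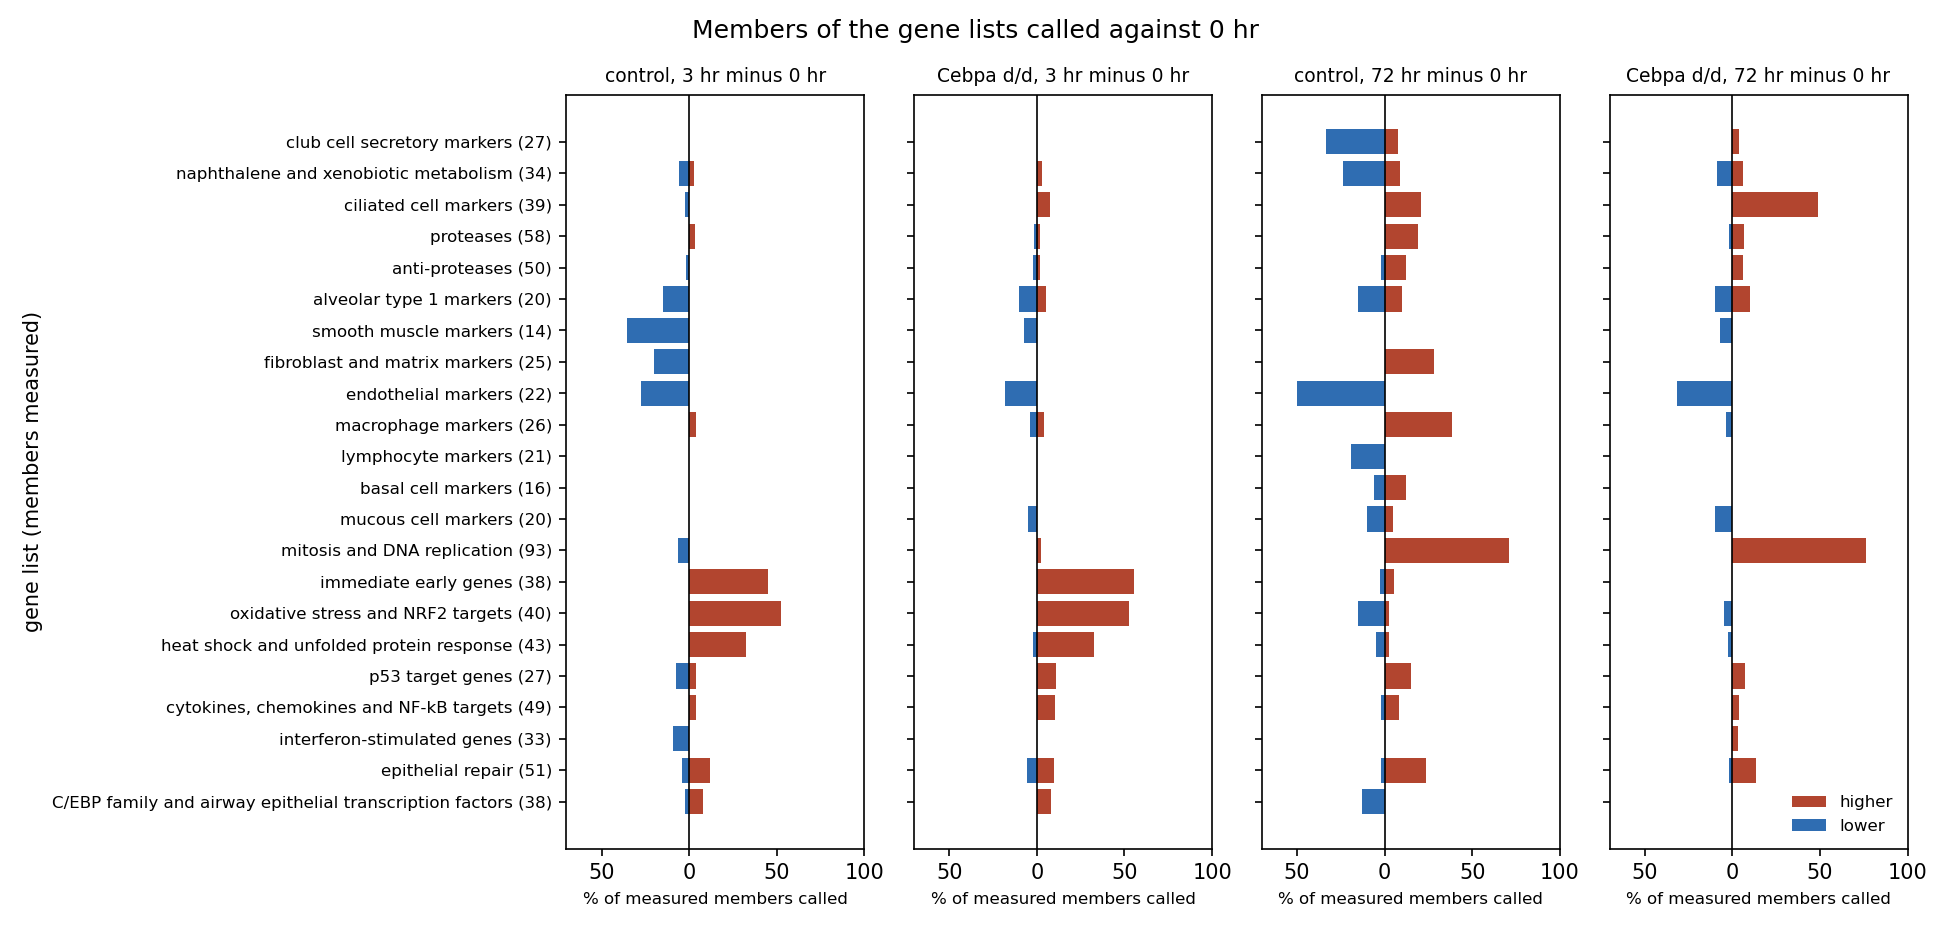
Percent of the measured members of each gene list that rose (red, to the right) or fell (blue, to the left) against 0 hr at an adjusted p under 0.05, in 4 panels for control and Cebpa d/d at 3 and at 72 hr; lists with at least 3 such members in any panel are drawn. Of 40 oxidative stress and NRF2 targets 21 rose at 3 hr in each genotype, and of 93 mitosis genes 66 in control and 71 in Cebpa d/d rose at 72 hr.

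The change from 0 to 72 hr in control cells asked how cells stood in recovery: 987 genes rose and 438 fell. Mitosis and DNA replication genes rose in 66 of 93 cases, 80 adjusted over the list alone (camera adjusted p = 2.29e-55, adjusted p = 0.0371 with an estimated correlation). Among them were Bub1b (1.60 ± 0.12, adjusted p = 4.68e-06), Ect2 (1.87 ± 0.17, adjusted p = 1.68e-05) and Mki67 (1.67 ± 0.21, adjusted p = 0.000307). Club cell markers fell in 9 of 27 cases and rose in 2, with 16 and 2 adjusted over the list alone (camera adjusted p = 7.01e-07, adjusted p = 0.256 with an estimated correlation). The paraoxonase gene Pon1 fell by 4.37 ± 0.81 (adjusted p = 0.00401), the sodium channel gene Scnn1b by 1.97 ± 0.36 (adjusted p = 0.00346) and Cyp2f2 by 0.76 ± 0.12 (adjusted p = 0.00182). Scgb1a1 stayed within the spread (0.02 ± 0.08, adjusted p = 0.926), at a level near the top of the scale where saturation was not examined. Xenobiotic metabolism genes fell in 8 of 34 cases and rose in 3, with 12 and 4 adjusted over the list alone, such as the glutathione transferase gene Gsta3 (-1.52 ± 0.26; camera adjusted p = 0.000615, adjusted p = 0.339 with an estimated correlation). Ciliated cell markers rose in 8 of 39 cases, 14 adjusted over the list alone, such as Dynlrb2 (1.07 ± 0.14; camera adjusted p = 1.41e-09, adjusted p = 0.293 with an estimated correlation). Pigr fell by 2.90 ± 0.29 (adjusted p = 4.9e-05). Epithelial repair genes rose in 12 of 51 cases and fell in 1, with 14 and 1 adjusted over the list alone, among them Clu (2.64 ± 0.29) and the keratin genes Krt7 (1.26 ± 0.24) and Krt19 (1.26 ± 0.23; camera adjusted p = 0.000617, adjusted p = 0.339 with an estimated correlation).

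In control cells by 72 hr some protease and anti-protease genes had risen. Of 58 proteases 11 rose, 17 adjusted over the list alone (camera adjusted p = 7.61e-06, adjusted p = 0.15 with an estimated correlation). They included the membrane protease gene Tmprss2 (0.88 ± 0.10, adjusted p = 0.000174), the lysosomal genes Lgmn (1.20 ± 0.18, adjusted p = 0.00113) and Ctsd (0.74 ± 0.14, adjusted p = 0.00508) and the matrix metalloprotease gene Mmp2 (0.89 ± 0.18, adjusted p = 0.00695). Of 50 anti-proteases 6 rose and 1 fell, 7 and 1 adjusted over the list alone (camera adjusted p = 0.00289, adjusted p = 0.154 with an estimated correlation). Spink5 rose by 3.59 ± 0.15 (adjusted p = 3.87e-10), the cystatin gene Cstb by 1.51 ± 0.20 (adjusted p = 0.000358) and the serpin gene Serpinb12 by 1.39 ± 0.21 (adjusted p = 0.00106). Slpi (0.75 ± 0.27, adjusted p = 0.101), Timp1 (1.86 ± 0.65, adjusted p = 0.0947) and Ctsk (1.30 ± 0.40, adjusted p = 0.0578) did not pass.

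Some markers of other cells changed in control cells at 72 hr as well. Macrophage markers rose in 10 of 26 cases, 14 adjusted over the list alone, such as Mrc1 (1.25 ± 0.25; camera adjusted p = 1.4e-08, adjusted p = 0.159 with an estimated correlation). Fibroblast markers rose in 7 of 25 cases, 11 adjusted over the list alone, such as Col6a3 (0.85 ± 0.18; 5.12e-06, adjusted p = 0.293 with an estimated correlation). Endothelial markers fell in 11 of 22 cases, 16 adjusted over the list alone, such as Kdr (-1.32 ± 0.26; camera adjusted p = 7.14e-11, adjusted p = 0.17 with an estimated correlation). Lymphocyte markers fell in 4 of 21 cases, 5 adjusted over the list alone (0.000315, adjusted p = 0.301 with an estimated correlation). Of the C/EBP family and airway transcription factors 5 of 38 fell, 6 adjusted over the list alone, such as Klf5 (-0.61 ± 0.13; camera adjusted p = 0.000427, adjusted p = 0.15 with an estimated correlation). Of 27 p53 target genes 4 rose, 5 adjusted over the list alone, such as Ckap2 (1.75 ± 0.27; camera adjusted p = 0.0463, adjusted p = 0.293 with an estimated correlation). Type 2 markers rose in 2 of 25 cases, 3 adjusted over the list alone (0.0312, adjusted p = 0.426 with an estimated correlation). Type 1 markers rose in 2 and fell in 3 of 20 cases, 4 and 4 adjusted over the list alone, and that list did not pass (0.886).

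All 72 hr arrays were from females. With sex as a covariate, chosen after the data were seen, 589 genes rose and 201 fell in control cells, 761 of which had passed without it. Mitosis genes then rose in 58 cases, proteases and repair genes in 8 each, macrophage genes in 5, anti-proteases in 4, fibroblast genes in 3 and p53 targets in 2. Club cell genes fell in 4, xenobiotic genes in 5, lymphocyte genes in 2 and transcription factors in 0. The p53 target and type 2 lists lost their call (camera adjusted p = 0.0698 for each). Of 90 named genes that passed in control at 72 hr, 59 did so without any 1 array and 68 with sex. Of those given values here only Klf5 lost its call with sex (adjusted p = 0.0512). The control count was 836 and 922 without control 0 hr replicates 2 and 3, and 614 and 841 without control 72 hr replicates 2 and 3. With each array centred on its median 1109 genes rose and 205 fell. Without the array labelled control 0 hr replicate 1, 1381 genes passed, and fewer endothelial (6), lymphocyte (0) and transcription factor genes (2) fell.

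From 0 to 72 hr 675 genes rose and 283 fell in Cebpa d/d cells. Mitosis genes rose in 71 of 93 cases, 84 adjusted over the list alone, such as Cenpf (1.86 ± 0.13, adjusted p = 1.57e-06) and Mki67 (1.62 ± 0.21, adjusted p = 0.000239), with camera adjusted p = 2.01e-68 (adjusted p = 0.0163 with an estimated correlation). Ciliated markers rose in 19 of 39 cases, 31 adjusted over the list alone, such as Dynlrb2 (1.38 ± 0.14, adjusted p = 1.96e-05; camera adjusted p = 1.07e-22, adjusted p = 0.176 with an estimated correlation). Proteases rose in 4 of 58 cases and fell in 1, 8 and 1 adjusted over the list alone, with Tmprss2 at 0.92 ± 0.10 (camera adjusted p = 0.00972, adjusted p = 0.43 with an estimated correlation). Anti-proteases rose in 3 of 50 cases over all genes and over the list alone, with Cstb at 1.03 ± 0.20 (adjusted p = 0.00522), and the list did not pass (camera adjusted p = 0.596). Spink5 was 5.35 ± 0.05 at 0 hr and 5.57 ± 0.24 at 72 hr (SD). Of the club cell list 1 of 27 rose and 0 fell in limma over all genes, and 2 rose and 11 fell adjusted over the list alone (camera adjusted p = 0.000109, adjusted p = 0.43 with an estimated correlation). Cyp2f2 did not pass (-0.42 ± 0.12, adjusted p = 0.0681), but without Cebpa d/d 72 hr replicate 1 it fell by 0.61 (adjusted p = 0.00051). Over all alternatives its adjusted p ran from 0.00051 to 0.344, the highest without Cebpa d/d 72 hr replicate 2. Xenobiotic genes rose in 2 and fell in 3 of 34 cases, 3 and 13 adjusted over the list alone (camera adjusted p = 0.000322, adjusted p = 0.43 with an estimated correlation). Endothelial markers fell in 7 of 22 cases, 18 adjusted over the list alone, with Ptprb at -0.83 ± 0.12 (camera adjusted p = 1.65e-14, adjusted p = 0.176 with an estimated correlation). Repair genes rose in 7 of 51 cases and fell in 1, 9 and 1 adjusted over the list alone, with Krt19 at 1.47 ± 0.23 (camera adjusted p = 0.00308, adjusted p = 0.542 with an estimated correlation). The largest falls were again in heart muscle genes, 27 of the 32 on the added list, such as Hamp (-4.88 ± 0.53) and Ttn (-3.51 ± 0.32), both of them higher in the Cebpa d/d arrays at 0 hr.

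With sex as a covariate 362 genes rose and 191 fell in Cebpa d/d at 72 hr, 527 of which had passed without it. Ciliated markers then rose in 7 cases, mitosis genes in 60, repair genes in 3, proteases in 2 and anti-proteases in 1, and xenobiotic genes fell in 0. Of 49 named genes that passed, 32 did so without any 1 array and 38 with sex. The count of 958 was 612 and 617 without Cebpa d/d 0 hr replicates 1 and 2, and 398 and 512 without Cebpa d/d 72 hr replicates 2 and 3. Several list counts rested on Cebpa d/d 72 hr replicate 1. Without it 11 club cell and 13 xenobiotic genes fell, and 8 protease, 5 anti-protease, 12 repair, 6 macrophage and 5 fibroblast genes rose. The fibroblast (camera adjusted p = 1.17e-05) and p53 target lists (0.0419) then passed as higher and the transcription factor list (0.0132) as lower.

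The interaction at 72 hr asked which genes changed differently between 0 and 72 hr in the 2 genotypes. It passed for 19 genes, all with a lower change in Cebpa d/d. Spink5 had the largest difference (-3.37 ± 0.21, adjusted p = 2.57e-07): it rose in control cells and not in Cebpa d/d cells. Orm2 (-2.26 ± 0.38, adjusted p = 0.0273) and Sectm1b (-2.07 ± 0.35, adjusted p = 0.0273) followed the same pattern. Pgam2 (-2.71 ± 0.33, adjusted p = 0.00177), Ttn (-2.61 ± 0.45), Csrp3 (-2.42 ± 0.38), Myl3 (-2.49 ± 0.42) and Lmod2 (-2.10 ± 0.35) are striated muscle genes, which were high in Cebpa d/d at 0 hr. On the added cardiac list 5 of 32 genes passed. Spink5 was the 1 of 50 anti-proteases that passed over all genes, 2 adjusted over the list alone (camera adjusted p = 0.00685, adjusted p = 0.555 with an estimated correlation). Of 58 proteases 0 passed limma (0.0163, adjusted p = 0.555 with an estimated correlation), and of the other lists that passed camera 0 members were called. At an unadjusted p under 0.05 there were 892 genes, fewer than the 997 expected by chance. No interaction passed for Cyp2f2 (0.34 ± 0.18), Slpi (-0.75 ± 0.37) or Mki67 (-0.05 ± 0.30), each with an adjusted p of 1. Without Cebpa d/d 72 hr replicate 1 the value for Cyp2f2 was 0.15.

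For the interaction at 72 hr, Spink5 and Pgam2 passed without any 1 array. The other 6 named genes each lost their call without at least 7 of the 18 arrays in turn, the array labelled control 0 hr replicate 1 among them (adjusted p up to 0.108). The count of 19 was 3 without that array, 4 without control 0 hr replicate 3, 4, 4 and 9 without control 72 hr replicates 1, 2 and 3. It was 7, 4 and 48 without Cebpa d/d 0 hr replicates 1, 2 and 3, and 3, 12 and 4 without Cebpa d/d 72 hr replicates 1, 2 and 3. Both genotypes shared 445 rising genes, against 33.4 for independent lists, and 60 falling genes, against 6.22, with a correlation of 0.689 across all genes. Here too the calls share the estimate of the spread of each gene, so 33.4 and 6.22 are not the overlap by chance.

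**Figure D3:**
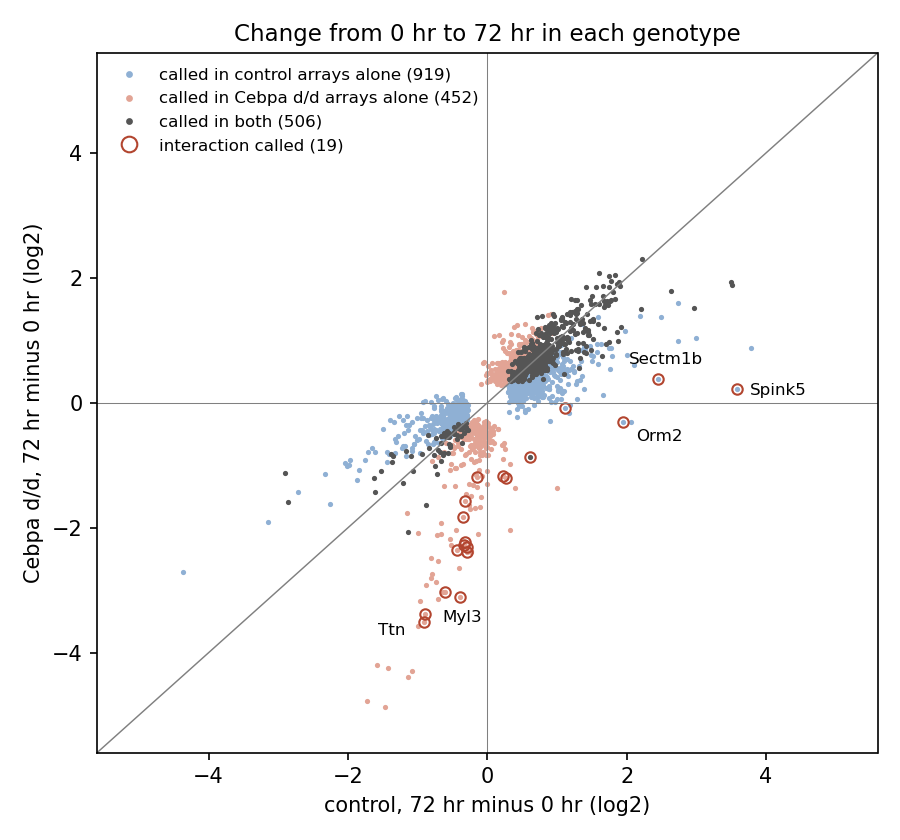
Log2 change from 0 to 72 hr of each gene in control arrays (horizontal axis) and in Cebpa d/d arrays (vertical axis), 3 arrays per group, with a grey line where both changes are equal; colours mark genes that passed in control alone (919), in Cebpa d/d alone (452) or in both (506), and circles mark the 19 genes whose interaction passed. Spink5 lies far below the line, with a change of 3.59 in control, and the labelled muscle genes Ttn and Myl3 lie below it with falls in Cebpa d/d.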

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

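The array labelled control 0 hr replicate 1 had Cebpa at 7.89, where the other 2 control arrays at 0 hr had a mean of 10.12. The test of a swap was chosen only after that value was seen. The other 2 tests also concern an array picked out by its values, so they were not fixed before the data were examined. A Cebpa d/d genotype in that array was tested on 28 genes that differed between genotypes at 3 and 72 hr, without Cebpa. On an axis from 0 for controls to 1 for Cebpa d/d it stood at 0.96, where the other controls stood at -0.02 to 0.02 and the Cebpa d/d arrays at 0.86 to 1.08. A swap of 2 arrays between the groups at 0 hr was excluded, since the highest of the 3 Cebpa d/d arrays lay 1.85 log2 units below the mean of the other 2 controls. Fewer airway epithelial cells were excluded, since 27 club cell genes deviated by a median of -0.01 (SD 0.76) where -1 or below was needed. A Cebpa d/d genotype under a control label could give the position of 0.96, which weights each gene by the size of its difference. Single named genes, picked after their values were seen, were mixed. In this array Lyz1 (7.86) and Lyz2 (10.21) lay within the range of the Cebpa d/d arrays at 0 hr. Lcn2 (7.71), Chia1 (8.3), Acoxl (6.45) and Abca3 (8.46) lay outside that range, on the side of the other 2 controls. A wrong label brought from outside these arrays and low Cebpa activity in a control animal were not tested separately.

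Transcripts of striated muscle were higher in Cebpa d/d arrays at 0 hr. The cardiac list, the skeletal list and the test of the genotype at every time were chosen only after values had been seen. Of 32 cardiac genes 20 were higher, with a median of 1.63 (SD 0.92; camera p = 1.38e-55, and p = 0.00033 with an estimated correlation), and the mean of the list was 9.48, 9.25 and 8.68 in the 3 Cebpa d/d arrays against 7.68, 7.97 and 6.88 in controls and 6.90 to 7.45 in the other 12 arrays. Cardiac muscle in the sampled tissue, such as the sleeves around pulmonary veins, may explain this, and 31 of the 32 genes lay higher. At 1.63 it was left open by the rule set for it: of the 6 most abundant members Nebl differed by -0.29, where 2 members under 0.25 were needed to exclude it. Skeletal muscle was excluded as the source of a rise of that size by a median of 0.23 (SD 0.30) over 22 genes. Still, 21 of the 22 lay higher (camera p = 2.98e-07, p = 0.0281 with an estimated correlation, fry p = 0.00834), so a small share of it stays open. The Cebpa d/d genotype at every time was excluded by medians of 0.06 at 3 hr (SD 0.33) and 0 at 72 hr (SD 0.29).

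The array labelled Cebpa d/d 72 hr replicate 1 stood apart from the other 2 of its group. The test of cells that kept Cebpa was chosen only after this was seen. The test of a smaller response also concerns an array picked out by its values. The position of this array on the axis from control 0 hr (0) to control 72 hr (1) over 1425 genes was 0.32. The other 2 of its group stood at 0.90 and 0.76, and control 72 hr arrays at 0.93 to 1.07. A smaller response to naphthalene could give 0.32, but this stayed open because the other 2 had to exceed 0.85 and one was at 0.76. The axis genes were chosen on the control arrays, which also set both ends of the axis. Control positions near 1 were thus fixed in advance, and Cebpa d/d arrays could fall short of 1 for that reason, so this limit could not decide. Cells that kept Cebpa in that array could give its Cebpa of 9.07: on 73 genotype genes it stood at 0.42, between controls (-0.06 to 0.06) and Cebpa d/d. An earlier axis of only 4 genes had put it at -0.63 with controls at -0.15 to 0.18, so that result depends on the genes chosen. Both axes were read among 72 hr arrays, so a smaller response could shift them too. Of genes picked after their values were seen, Lyz1 (8.38), Lyz2 (10.38), Lcn2 (6.22), Acoxl (6.24) and Abca3 (8.14) lay below all control 72 hr arrays. Pon1 (8.82) was near its Cebpa d/d level at 0 hr (8.57 to 9.05), against 4.48 and 4.92 in the other 2 arrays. The test therefore cannot tell kept Cebpa from a smaller response.

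Other splits of the arrays between the groups were drawn for each count of genes that passed, a test chosen before the results were seen. For the mean genotype difference over the 3 times, the real split gave 61 genes, the most of 100 splits, rank 1, with 7 the highest other, so an arbitrary grouping was excluded. For the interaction at 72 hr the real 19 ranked 2 of 100, where the highest other split gave 22 and moved the array labelled control 0 hr replicate 1 among others. For the interaction at 3 hr the real 0 was matched or passed by all 100 splits, with 33 the highest. With 10 splits a share under 0.05 cannot be reached: the genotype difference gave 67 at 0 hr (highest other 22), 3 at 3 hr (7, so the real split ranked 2) and 14 at 72 hr (1). Changes in control gave 697 at 3 hr (44) and 1425 at 72 hr (1), and changes in Cebpa d/d gave 874 at 3 hr (0) and 958 at 72 hr (1).

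Some changes over time differed between the genotypes, in size or in direction. At 3 hr, the interaction of lists gave a median of 0.46 for ciliated (camera adjusted p = 4.29e-15), 0.20 for smooth muscle (0.0172), 0.10 for fibroblast (0.0172), 0.13 for mitosis (0.000488) and 0.31 for interferon-stimulated genes (2.28e-05), each with an adjusted p of 0.8 with an estimated correlation. At 72 hr, 19 genes differed in their change, and the named ones were Spink5 at -3.37, Pgam2 at -2.71, Ttn at -2.61, Myl3 at -2.49, Csrp3 at -2.42, Orm2 at -2.26, Lmod2 at -2.10 and Sectm1b at -2.07. List medians for that interaction were 0.21 for ciliated (camera adjusted p = 3.57e-05), -0.13 for proteases (0.0163), -0.085 for anti-proteases (0.00685) and -0.22 for alveolar type 2 genes (0.00685). They were -0.13 for smooth muscle (0.0418), -0.18 for fibroblast (0.00178), -0.31 for macrophage (2.84e-05), -0.048 for heat shock and unfolded protein (0.0147), 0.37 for interferon-stimulated (1.59e-06) and 0.10 for C/EBP family and airway transcription factor genes (0.0185). With an estimated correlation these adjusted p values ran from 0.555 to 0.833. Without the array labelled control 0 hr replicate 1 the interferon-stimulated list no longer passed at 3 hr (0.506) or 72 hr (0.288), nor did smooth muscle (0.0647) and fibroblast (0.194) at 3 hr or heat shock (0.0761) and transcription factor genes (0.104) at 72 hr. Lymphocyte (0.0262) and neuroendocrine genes (0.0261) then passed at 3 hr. Without Cebpa d/d 72 hr replicate 1 the 72 hr interaction no longer passed for proteases (0.524), anti-proteases (0.163), type 2 (0.208), smooth muscle (0.946), fibroblast (0.524), heat shock (0.348) and transcription factor genes (0.348), and it passed for mitosis genes (2.57e-11). At 3 hr it then passed for club cell (0.0228), xenobiotic (0.0232), transcription factor (0.029), immediate early (0.0463) and p53 target genes (0.0463).

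Probe sets with several gene symbols or none, which were outside the comparisons, also passed the test: 108 for the change at 3 hr and 335 at 72 hr in control, and 186 at 3 hr and 282 at 72 hr in Cebpa d/d.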

How the results depend on the processing

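For the genotype difference at 0 hr the count of 67 became 29 with genes below the median level left out, 355 with array weights, 1 with only the groups of the contrast in the fit, 201 without both arrays that stood apart and 271 at an unadjusted p with 1.5-fold change; leaving out each array in turn gave 30 to 153. At 3 hr the count of 3 became 0, 11, 7 (0 of them shared), 20 and 120 under the same settings in the same order, and 1 with each array centred, with 1 to 15 over single arrays left out. At 72 hr the count of 14 became 7, 88, 6, 23 and 167, with 12 to 20 over single arrays. The mean over the 3 times gave 61 genes, 431 with array weights and 228 without both arrays, with 22 to 201 over single arrays. The change at 3 hr in control gave 697, 55 with only its groups in the fit and 332 without both arrays, with 231 to 1414 over single arrays; in Cebpa d/d it gave 874, with 402 to 994. The change at 72 hr in control gave 1425, 3133 with array weights and 790 with sex as a covariate, with 614 to 1633 over single arrays. In Cebpa d/d it gave 958, 1981 with array weights, 553 with sex and 1441 without both arrays, with 398 to 1272 over single arrays. The interaction at 3 hr gave 0, 24 with array weights and 289 at an unadjusted p with 1.5-fold change, with 0 to 44 over single arrays. The interaction at 72 hr gave 19, 8 without genes below the median level, 69 with array weights, 4 with only its groups, 3 without both arrays and 286 at an unadjusted p with 1.5-fold change, with 3 to 48 over single arrays. Of 270 list tests 96 passed at the preset correlation, 3 with an estimated correlation, 28 with fry and 89 to 110 over single arrays left out. Of 292 named values that passed 0 changed sign. Of these, 247 still passed without both arrays, 248 with sex and 260 with the replicate block. With only the groups of the contrast in the fit 184 of 282 still passed and 98 did not, and over single arrays left out 625 of 5256 calls were lost. With the replicate number as a block the 10 counts were 62, 2, 17, 46, 528, 1246, 740, 874, 0 and 13, and 95 lists passed. Of 45 pairs of arrays with the same replicate number in 2 groups, 7 correlated above 0.1 in their deviations from the group mean (-0.288 to 0.199). Among 9 such pairs of the 2 genotypes at the same time, 3 did (-0.283 to 0.199). Arrays with different numbers were not compared, so whether the numbers pair arrays stays open. Counts moved with the settings, and the cause was not tested. The size of difference that can be found is limited by 3 arrays per group, and signal over background was not examined.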

Other observations

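Some lists passed the set test with at most 3 members called. In control cells by 3 hr neutrophil markers lay higher (median 0.28, 1 of 18 rose, camera adjusted p = 0.00245, adjusted p = 0.353 with an estimated correlation), while ciliated markers lay lower (median -0.26, 1 of 39 fell, 3.17e-06, adjusted p = 0.512 with an estimated correlation). Xenobiotic metabolism (1 rose and 2 fell of 34, 0.036) and lymphocyte genes (0 of 21 called, 0.0356) lay lower as well, and neither list passed without the array labelled control 0 hr replicate 1 (camera adjusted p = 0.153 and 0.544). By 3 hr in Cebpa d/d cells fibroblast (0.000197), lymphocyte (0.00141), alveolar type 1 (0.00792), smooth muscle (0.016), interferon-stimulated (0.0166) and alveolar type 2 genes (0.0344) lay lower by camera adjusted p, all over 0.5 with an estimated correlation. Of these, 1 type 1 gene rose and 2 fell, 1 smooth muscle gene fell and 0 of the other 4 lists passed in limma over all genes. In this contrast 3435 genes had an unadjusted p under 0.05, where 997 are expected by chance. Adjusted over the list alone 7 type 1 and 5 fibroblast genes fell. At 72 hr neutrophil markers lay higher in control (median 0.37, 0 of 18 called, 0.0312) and interferon-stimulated genes lower (median -0.37, 0 of 33 called, 4.27e-05), the latter not without the array labelled control 0 hr replicate 1 (0.249). Macrophage markers in Cebpa d/d at 72 hr lay higher with 0 of 26 rising and 1 falling (0.0204), while heat shock (7.89e-05) and lymphocyte genes (0.000968) lay lower. With an estimated correlation none of these lists passed. With sex as a covariate, chosen after the data were seen, sex-linked transcripts passed camera for the genotype difference at 3 hr (0.0107), the change at 3 hr in control (0.0161) and the interaction at 3 hr (0.00295). Immediate early genes then passed for the change at 72 hr in Cebpa d/d (0.0456) and the interaction at 3 hr (0.0403), and transcription factor genes for the latter (0.0496).

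Some of the largest changes in control cells at 72 hr were in genes outside the lists. The acute phase gene Orm1 rose by 3.79 ± 0.58 (adjusted p = 0.00115), the surface protein gene Psca by 3.51 ± 0.50 (adjusted p = 0.000692), the peptide hormone gene Ghrl by 3.50 ± 0.41 (adjusted p = 0.00017) and Tdo2, which breaks down tryptophan, by 2.73 ± 0.31 (adjusted p = 0.000153). Scgb1c1, a secretoglobin, fell by 3.16 ± 0.61 (adjusted p = 0.00498). Wfdc3, a gene with an inhibitor-like domain, rose by 2.22 ± 0.28 (adjusted p = 0.000316) in control and by 2.30 ± 0.28 (adjusted p = 0.000151) in Cebpa d/d.

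Among the 65 genes higher in Cebpa d/d at 0 hr, 45 were outside the cardiac list. Of these 45, 21 correlated above 0.5 with the cardiac score in the 12 arrays of the other groups, against 9.8% of all genes.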
